A study of Caenorhabditis elegans with 2 samples.

How the data were processed

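The samples were 2 biological replicates of ChIP-seq on whole L1 larvae of mixed sex, with an antibody that the labels list for CES-1 and a strain they describe as carrying tagged CES-1. The labels say that the replicates are biological, without giving cultures or dates. Control libraries were not analysed here. The deposited peak lists came in 2 genome builds, ce10 and ce11, each with 4 lists. There was 1 list per replicate, 1 from both replicates together, and 1 that the authors call optimal, which per the deposited notes rests on the irreproducible discovery rate (IDR) between replicates. Not all optimal peaks overlapped a peak in the list of replicate 2, as given below. The deposited notes say that the lists were made from alignments and 1 control file. The peak caller, its version and the IDR threshold were not given in the sources used here.

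Each deposited list gives a signal value per peak, in a unit that the authors do not state, and it was used only to rank and describe peaks within a list. The lists also give the authors' −log10 q value, which was 2.90 for every optimal peak of ce11 and so could not rank them. A further deposited column, of the unit the file format defines as other, gives the summit as an offset from the peak start. Peak lists hold no read counts, so the depth of each replicate is unknown, and the intervals below cover counting of peaks only. For a count of 0 the upper limit given is 3 counts of the total, not an exact interval. Per the deposited lists, peaks were 344 bp wide at the median in replicate 1, 380 bp in replicate 2 and 324 bp in the optimal list. The optimal list of ce10 held 508 peaks, and each build was analysed on its own, with no conversion of coordinates.

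Sequence and genes came from the WBcel235 assembly, which has the chromosomes of ce11, with gene models of Ensembl release 115, and were used with the ce11 lists only. All coordinates are in ce11 and counted from 1. The promoter window ran from 1000 bp upstream to 200 bp downstream of an annotated 5′ end of a protein-coding transcript. Other summits were placed in turn in 5′ UTR, coding exon, 3′ UTR, intron or intergenic sequence. Shares were compared with 10000 random placements on the same chromosomes, and the overlap of replicates, of at least 1 bp, with 1000. The smallest p these can give is 0.0002 and 0.001. Both are called a permutation of peak positions below, but no positions were shuffled. Each peak was placed independently of the others and with equal probability along its chromosome. Motif shares within 100 bp of the summit were compared with windows 1000 bp to each side by a sign-flip permutation test of 100000 draws, with 2000 bootstrap draws for the interval. Gene lists were compared with other protein-coding genes by Fisher's exact test. Adjusted p-values are Benjamini-Hochberg values, with a threshold of 0.05. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

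The hexamer test differs from the one fixed before the data were examined. That one was a McNemar test over every pair of a summit and a flank, which counts the same summit again for its other flank, as if independent. On 100 simulated lists of 371 random positions it gave at least 1 hexamer past the threshold in 71. It was replaced, after its result on the data had been seen, by an exact test that compares each summit with both of its flanks together, which gave any such hexamer in 3 of the 100. The replaced test called 531 hexamers in the data and the reported one 317. The simulated positions were drawn at random, with no difference in GC content built in between summits and flanks. In the data it was 44.04% and 36.3%, so the simulation does not cover hexamers that differ through base composition.

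The other tests were also tested on simulated data. On the same 100 lists the Snail E-box test gave a p under 0.05 in 3 and the promoter test in 9. When 20% of 371 random positions were given a Snail E-box, the difference recovered was 18.9 percentage points and the planted hexamer ranked 1. When 10 ribosomal protein genes were given a peak, that list alone passed among the 39. When 150 of 371 peaks were kept and moved by at most 100 bp, 151 were found shared.

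The genes named were set by a rule fixed before the data were examined. It takes the protein-coding genes nearest to the 20 strongest optimal peaks, and all 8 genes of a list from the literature on CES-1. It adds up to 4 members with the strongest peak of each gene list past the threshold, and of the lists for programmed cell death, asymmetric division, cell cycle, and serotonergic and NSM neurons. It also takes the genes nearest to the 3 highest peaks of each replicate outside the strongest peaks of the other. Alternatives fixed in the same way were other overlap rules and numbers of peaks, other windows, flanks and backgrounds, a stricter threshold, the ce10 lists where no genome sequence was needed, and leaving out each replicate, by using the 371 strongest peaks of the other one. Leaving out the peaks around unc-42 and a few others were added later.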

Results

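The series holds chromatin immunoprecipitation sequencing (ChIP-seq) of whole Caenorhabditis elegans L1 larvae, the stage that hatches from the egg. The labels name a strain that carries CES-1, a zinc finger transcription factor of the Snail family, joined to a tag that includes green fluorescent protein. There were 2 biological replicates of 1 group, so no condition was compared with another. The deposited peak lists of genome build ce11 held 28161 peaks for replicate 1, 30000 for replicate 2 and 14076 for both together. The authors label the list from both together as peaks and background, meant as input for IDR. Its entries are therefore not all bound sites. The list of replicate 2 held 30000 in ce10 as well. A stricter list, called optimal by the authors, held 371 peaks, with signal values from 31.5 to 302. These 371 were the strongest peaks of the list made from both replicates. The lists give no read counts, so the depth of each library is unknown. All peak signals below are the authors' values, and the intervals on shares are exact binomial intervals over peaks.

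The ces-1 gene itself (WBGene00000468, chromosome I, 8633897 to 8636169, plus strand) had no optimal peak within 2000 bp. Its strongest peak in the list from both replicates ranked 1827, with a signal of 17.97. In replicate 2 a peak downstream of the gene, at 8636532 to 8636911, ranked 357 with a signal of 14.9. In replicate 1 the strongest peak within 2000 bp of the gene lay at another site, at 8633629 to 8633972 around the gene's start. It ranked 24872 of 28161, with a signal of 3.75, near the lowest of that list, 3.46. The other 7 genes fixed beforehand from the literature on CES-1 also had no optimal peak within 2000 bp. They were ces-2, a bZIP factor gene upstream of ces-1 in cell death specification, egl-1, the BH3-only activator of programmed cell death, the kinase gene pig-1, the phosphatase gene cdc-25.2, dnj-11, and the bHLH factor genes hlh-2 and hlh-3. The best rank in the list from both replicates was 2315 for pig-1, 6767 for cdc-25.2, 7274 for ces-2 and 12781 for hlh-2, while egl-1, dnj-11 and hlh-3 had no peak in it. In replicate 1 the strongest pig-1 peak ranked 906, at 519442 to 519785 on chromosome IV. From the share of other genes with an optimal peak in the promoter window, 0.0685 of the 8 genes were foreseen to have one. The lack of optimal peaks at a list this small therefore says little.

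The strongest signal of both replicates lay at another gene. The peaks ranked 1, 2 and 3 in replicate 1, in replicate 2 and in the optimal list were at unc-42 (WBGene00006778, chromosome V, 9764534 to 9769391, minus strand), which encodes a homeodomain transcription factor of neurons. The optimal peak ranked 1 spanned 9765696 to 9765946, with a signal of 302, against 219 in replicate 1 and 89.5 in replicate 2. The peak ranked 2, at 9769427 to 9769712, had its summit 220 bp upstream of an annotated 5′ end and a signal of 248. The peak ranked 3, at 9768928 to 9769125, lay in an intron and had a signal of 183. The peak ranked 12, with a signal of 90.8, was at unc-42 too, and the peak ranked 6 was at the neighbouring gene F46B6.2, with a signal of 108. Weak peaks were also denser there, as the 40 kb around unc-42 held 24 in replicate 1 and 25 in replicate 2 outside the optimal peaks, against genome medians of 11 and 12.

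**Figure D1:**
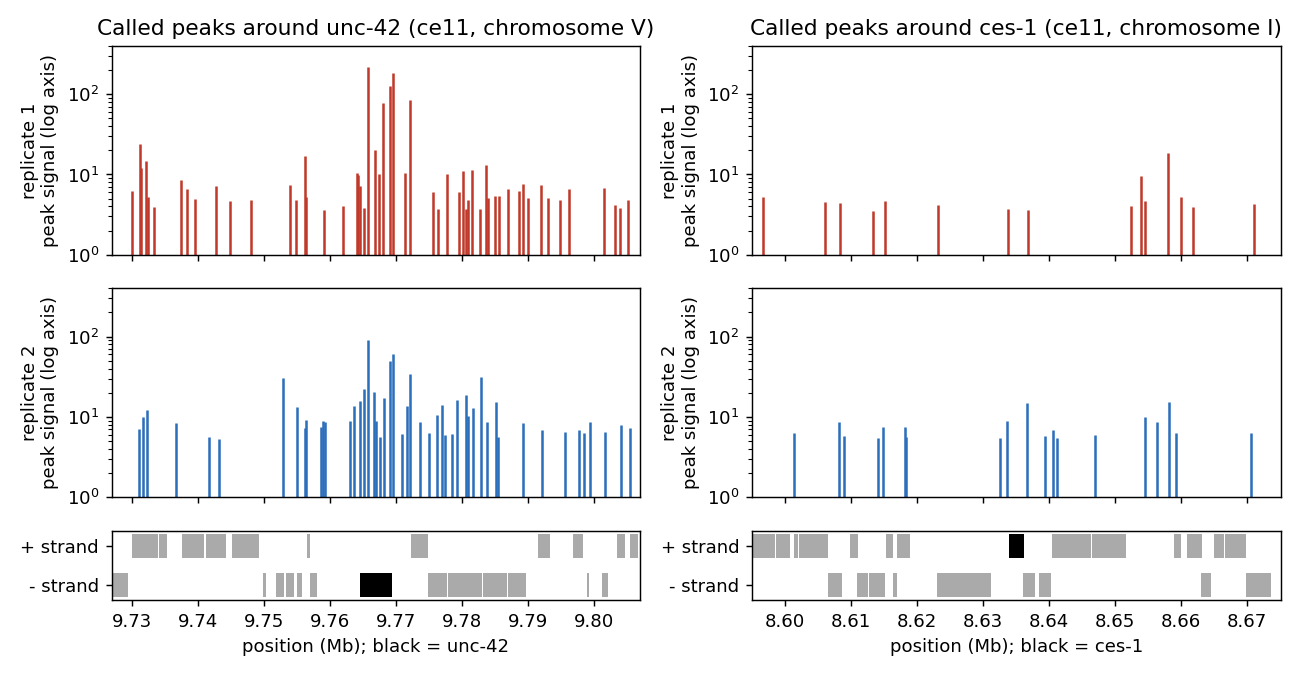
Called peaks around unc-42 and around ces-1, drawn over windows of the same width, with position in Mb on the horizontal axis and peak signal on a log vertical axis, one line per peak and 1 replicate in each upper panel. Protein-coding genes are drawn below by strand. The tallest line at unc-42 is at 219 in replicate 1 and at 89.5 in replicate 2, while the tallest within 2000 bp of ces-1 is at 3.75 and 14.9.

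Among the other 20 strongest optimal peaks, the one ranked 4 lay 268 bp upstream of rpl-3, which encodes a protein of the large ribosomal subunit, with a signal of 125. The peak ranked 5 lay 81 bp upstream of C37A2.8, with a signal of 122. The peaks ranked 7 and 8 were on chromosome X, nearest to W02H3.3 and in an intron of irk-3, a potassium channel gene, with signals of 107 and 99.8. Further peaks in this set were nearest to ZK1248.17 (signal 97.7), F28E10.1 (97.3), the ATPase gene cdc-48.1 (93.5), pqn-41 (87.0), the neuronal calcium sensor gene ncs-2 (81.5), cest-16 (79.9) and fic-1 (79.2). The set ended with F20B6.9 (79.0), the kinase gene mrck-1 (78.4), nspc-17 (78.2) and the polarity kinase gene par-1 (76.7). The par-1 peak ranked 9 in replicate 1 and was missing from the list of replicate 2. Of the 20 peaks, 1 had the E-box CAGGTG within 100 bp of its summit, the peak nearest to F20B6.9.

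The replicates were compared through their 371 strongest peaks. Of those of replicate 1, 94 overlapped a peak among the 371 strongest of replicate 2, which is 25.34% (95% interval 20.99 to 30.1). Random placement on the same chromosomes gave 0.266% on average and at most 1.62% (one-sided permutation of peak positions, p = 0.001, the smallest that 1000 placements can give). The optimal list followed replicate 1 more closely, as 300 of its peaks (80.9%) overlapped the 371 strongest of replicate 1 and 32.1% those of replicate 2. Against the whole lists, all 371 overlapped a peak of replicate 1 and 329 (88.7%) a peak of replicate 2. The optimal list thus holds peaks without a counterpart in replicate 2. Over the 304 optimal peaks with a summit of both replicates inside them, Spearman's rho between the replicates' signals was 0.155 (95% interval 0.0431 to 0.263), which is a description across peaks that are not independent. Pearson's r of the log2 signals was 0.349. The optimal peaks are those with the highest signal in the list from both replicates. Such a selection can lower the correlation, so these values do not measure agreement over all peaks. The highest peaks found among the 371 strongest of replicate 1 and not among those of replicate 2 were nearest to cdc-48.1, par-1 and rpl-12. The cdc-48.1 peak ranked 8 in replicate 1 and 538 in replicate 2, and the rpl-12 peak ranked 15 and 1471. For replicate 2 they were nearest to W03G11.4, F46B6.5 and F58E6.6, of which the last had no overlapping peak in replicate 1. F46B6.5 and F58E6.6 both lie near unc-42 on chromosome V. The 276 peaks of replicate 2 outside the shared set had 26.4% of their summits in coding exons, against 0.722% for the 277 of replicate 1.

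**Figure D2:**
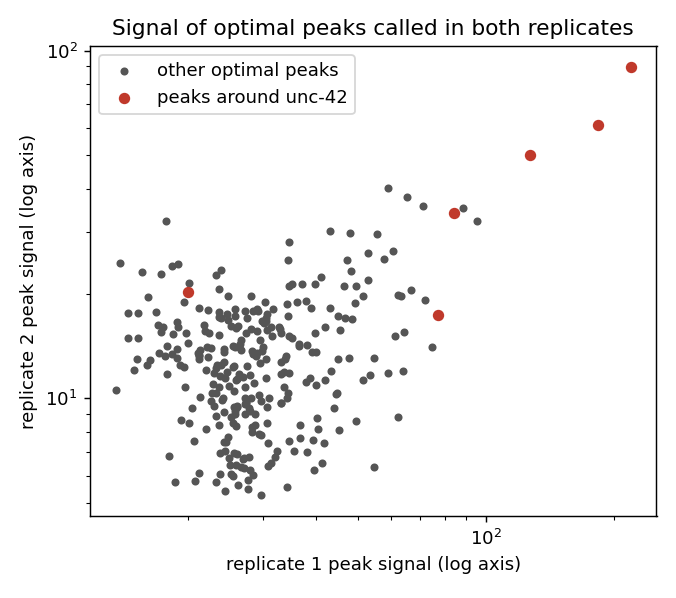
Signal of each optimal peak called in both replicates, with replicate 1 on the horizontal and replicate 2 on the vertical axis, both log axes. Each point is a peak, and red points are the peaks around unc-42. The 3 points at the upper right are the unc-42 peaks ranked 1, 2 and 3, and the others spread with a rho over all points of 0.155. All points were selected for high signal in the list from both replicates, which can lower rho.

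Optimal peaks lay near the 5′ ends of genes more often than random positions. Of 371 summits, 146 (39.4%, 95% interval 34.3 to 44.5) fell from 1000 bp upstream to 200 bp downstream of a 5′ end of a protein-coding gene, against 25.6% at random (two-sided permutation of peak positions, p = 0.0002, the smallest possible). The excess was smaller in the 371 strongest peaks of replicate 2 alone, at 31.3% against 25.9% (permutation of peak positions, p = 0.0232), in a test that gave a p under 0.05 for 9 of 100 simulated random lists. Intergenic sequence outside these windows held 121 summits (32.6% against 25.5%, adjusted permutation p = 0.0032). Coding exons held 5 summits (1.35% against 18.6%, adjusted permutation p = 0.0006), and introns held 94 (25.34% against 27.4%, adjusted p = 0.473 in the same test). The 3′ UTRs held 3 summits and the 5′ UTRs 2. The median distance to the nearest 5′ end was 1200 bp, and 171 of 19973 protein-coding genes had a peak in their promoter window.

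**Figure D3:**
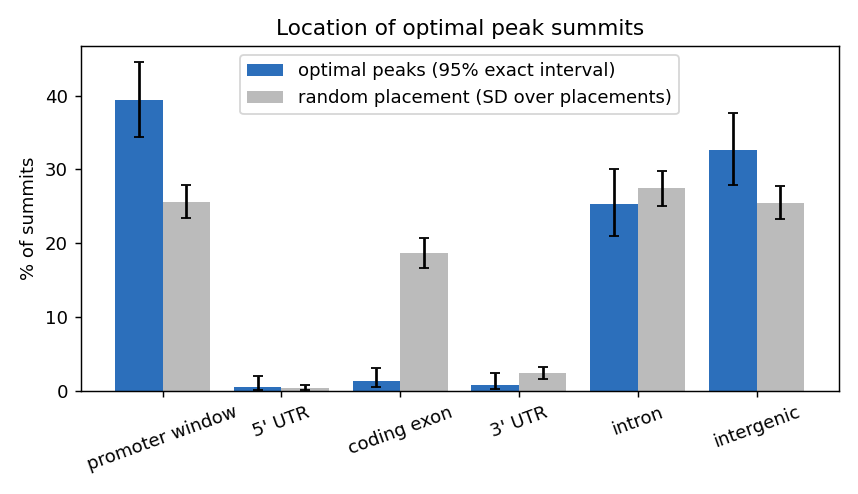
Share of optimal peak summits in each class of sequence, in percent of 371 summits, beside the share at random positions. Blue bars carry the exact 95% interval and grey bars the SD over placements. Promoter windows hold 39.4% against 25.6% at random and coding exons 1.35% against 18.6%.

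Chromosome X held 96 of the 371 optimal peaks, 25.9% (95% interval 21.5 to 30.6), against 13.7% of protein-coding genes (exact binomial test, two-sided, p = 4.85e-10). X makes up 17.7% of the sequence length of the 6 chromosomes, which is also below the share of peaks (exact binomial p = 7.41e-05). Weak peaks were frequent on X too, at 19.01% of the 4692 weakest peaks of the list from both replicates, and the optimal peaks lay above that (Fisher's exact test, two-sided, p = 0.00173, chosen after the shares were seen). The peaks of replicate 2 outside the shared set did not show this, with 19.2% on X against 18.3% of the weaker peaks of that replicate (Fisher's exact test, two-sided, p = 0.696). On X, 30.2% of the peaks lay in promoter windows, against 42.5% on the autosomes, while random positions gave 21.8% and 27.2%.

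The Snail E-box CAGGTG, the sequence bound by the Snail family, was rarer at the summits than beside them. It lay within 100 bp of 9 of 371 summits, 2.43% (95% interval 1.12 to 4.55), against 7.28% of windows 1000 bp away. The difference was -4.85 percentage points (95% bootstrap interval -7.28 to -2.43, two-sided sign-flip permutation p = 0.00011). It was smaller for the 146 summits in promoter windows when set against random positions in the same windows. There the shares were 1.37% and 3.72% (difference -2.35 points, 95% bootstrap interval -4.20 to -0.156, permutation p = 0.0154). In the 371 strongest peaks of replicate 2 alone the shares were 6.20% and 6.06% (difference 0.135 points, permutation p = 1.0). Of the 10 distinct E-box hexamers, 3 passed the threshold, all lower at summits, and these were CAGGTG itself, CAACTG (4.58% against 10.4%, adjusted permutation p = 0.0009) and CACGTG (1.62% against 4.85%, adjusted p = 0.0042). CACATG was in 11.1% of summit windows and 6.74% of flanks, which did not pass (adjusted permutation p = 0.077). Of the 123 strongest optimal peaks 4 held the Snail E-box, and of the 123 weakest 2 did (Fisher's exact test, two-sided, p = 0.684).

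Instead, GA-rich hexamers marked the summits. In a scan of 2080 hexamers within 50 bp of the summit, 317 passed an adjusted p of 0.05, of which 177 were commoner at summits and 140 rarer. AGAGAG led, present at 26.1% of summits and 5.26% of flanks (exact matched test, adjusted p = 2.9e-18), followed among the commoner hexamers by GAGAGA (26.4% and 6.20%) and CGTCTC (15.6% and 2.96%). AT-rich hexamers such as AAAAAT (17.3% and 43.9%) and TTAAAA (6.47% and 27.6%) were rarer at summits. The GC content was 44.04% at summits and 36.3% in flanks. Windows matched on GC content were compared for a few sequences only, so how many of the 317 follow base composition is unknown. With the 371 strongest peaks of replicate 2 alone 67 hexamers passed, 28 commoner and 39 rarer at summits, led by the rarer AAAAAT, and 58 of them were among the 317. With the 185 strongest optimal peaks 123 passed.

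**Figure D4:**
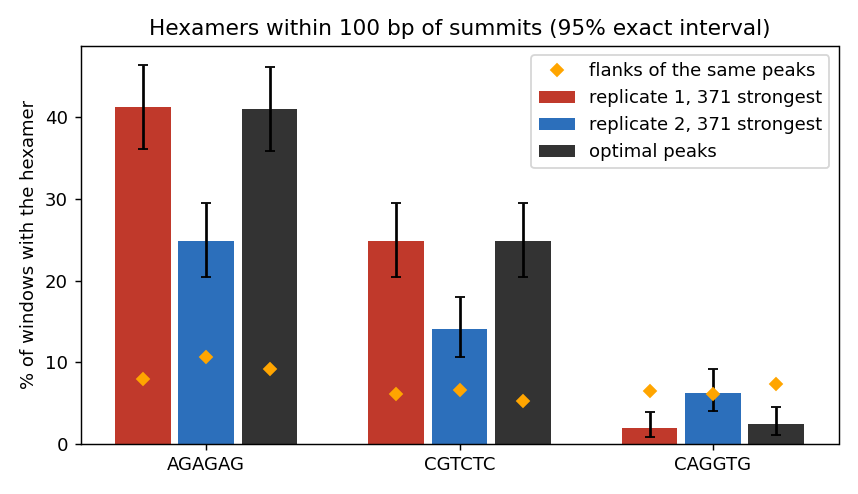
Share of peaks with each hexamer or its reverse complement within 100 bp of the summit, in percent, for the 371 strongest peaks of each replicate and for the optimal peaks. Bars carry exact 95% intervals and diamonds mark the mean share in the flanks of the same peaks. AGAGAG is in 41.2% of replicate 1 windows, 24.8% of replicate 2 windows and 41.0% of optimal windows, and CAGGTG lies below its flanks in replicate 1 and in the optimal list, at 1.89% and 2.43%.

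Of 39 gene lists fixed before the data were examined, 2 passed the threshold. Genes of ribosomal proteins were overrepresented, with a peak in the promoter window of 9 of 78 (11.5%) against 0.814% of other genes (odds ratio 15.9, Fisher's exact test, two-sided, adjusted p = 8.58e-07). The strongest of these peaks were at rpl-3 (signal 125), rpl-12 (73.3), rpl-35 (66.3) and rps-28 (53.3). The rpl-12 peak spanned 13240549 to 13240872 on chromosome IV. In the 371 strongest peaks of replicate 2 alone 1 of the 78 genes had a peak (Fisher's exact test, adjusted p = 1.0). Chemoreceptor genes, a large family of sensory receptors, were underrepresented, with 0 of 875 at a peak where 7.83 were foreseen from other genes (Fisher's exact test, adjusted p = 0.0192), and a count of 0 allows a share of up to 0.343%. With the 371 strongest peaks of replicate 2 the chemoreceptor count was again 0, without passing the threshold (Fisher's exact test, adjusted p = 0.288). It did not pass either with windows from 500 bp upstream to 100 bp downstream or with the 185 strongest optimal peaks (Fisher's exact test, adjusted p = 0.218 and 0.682).

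The lists tied to what CES-1 is known for did not pass. Neither programmed cell death genes (0 of 21), nor cell cycle genes (0 of 25), nor genes of serotonergic and NSM neurons (0 of 13) had a peak in a promoter window, and of the asymmetric division genes 1 of 19 did, par-1 (Fisher's exact test, adjusted p = 0.651). Counts of 0 in lists this small say little, since fewer than 1 gene was foreseen in each. Wnt signalling genes had 2 of 25 at a peak (Fisher's exact test, adjusted p = 0.25), the receptor gene lin-18 and the Dishevelled gene mig-5, both named after their values were seen. Of the pan-neuronal genes 1 of 17 had a peak (Fisher's exact test, adjusted p = 0.651). With windows from 2000 bp upstream to 500 bp downstream both lists passed, with 3 Wnt signalling genes and 3 pan-neuronal genes (Fisher's exact test, adjusted p = 0.0477 and 0.0204).

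Among genes of non-coding RNA, the small nuclear RNA class stood out. A summit lay within 200 bp of such a gene for 4 of 371 peaks, 1.08% (95% interval 0.295 to 2.74) against 0.0564% at random (permutation of peak positions, adjusted p = 0.001, Benjamini-Hochberg over 5 classes). All 4 were at sls genes, which encode the SL2 spliced leader RNA joined to downstream messages of operons, and they are named after the result was seen. The peak at sls-2.1 (chromosome II, 5844674 to 5844997) ranked 9 with a signal of 97.7, sls-2.4 ranked 22, sls-2.2 ranked 28 and sls-2.6 ranked 161. In replicate 2 they ranked 4, 18, 34 and 21175, in the same order. The sls-2.1 peak is the one given above as nearest to ZK1248.17. Transfer RNA genes were near 3 summits (adjusted permutation p = 0.577), or 5 in the 371 strongest peaks of replicate 2 alone, which passed (adjusted permutation p = 0.029),. Small nucleolar RNA genes were near 1 summit, and ribosomal RNA and microRNA genes near 0, which allows up to 0.809% of peaks.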

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

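The alternatives without the peaks around unc-42, the replaced hexamer test, the other windows for the E-box hexamers, the weakest pooled peaks, the GC-matched positions and all values for TAATTA were chosen after the data were seen. The overlap of replicates (19.7% to 28.6%) and the promoter share (31.3% to 42.9% with 1 replicate left out) kept their direction under all alternatives run. So did the share on X (21.3% to 28.03%), while the E-box share by peak strength stayed on its side of the threshold. The weakest pooled peaks also lay above the share of genes on X, at 19.01%, but they are a background and do not count as an alternative. For each change that follows, the cause was not tested unless stated. The Snail E-box difference, -4.85 percentage points as first tested, was -8.09 with 200 bp windows and -2.56 with 50 bp windows. It was -3.23 with flanks 500 bp away and -2.35 with positions in the same promoter windows, and passed the threshold in each of these settings. With 1 replicate left out it lay between -4.58 and 0.135 percentage points, the latter without replicate 1. TAATTA, -2.16 points as first tested, passed the threshold as rarer at summits with 200 bp windows (-6.60), flanks 500 bp away (-4.31), positions in the same promoter windows (-4.94) and the 185 strongest peaks (-7.03), turned to 1.63 without passing against promoter positions matched on GC content, and ranged from -4.31 to -1.21 with 1 replicate left out, the former, without replicate 2, past the threshold (permutation p = 0.0133). The number of E-box hexamers past the threshold was 5 with 200 bp windows and 2 with 50 bp windows, against 3. The hexamer count, 317, was 531 with each summit paired with each flank as if independent, a test that simulated lists showed to call too many. It was 485 with 100 bp windows, 123 with the 185 strongest peaks, where fewer peaks were tested, and 67 to 316 with 1 replicate left out. The gene lists past the threshold, 2, were 1 with windows of 500 and 100 bp (chemoreceptors lost), 4 with 2000 and 500 bp (adding Wnt signalling and pan-neuronal), 3 by the nearest 5′ end (adding pan-neuronal, 4 of 17, Fisher's exact adjusted p = 0.00222), 1 with the 185 strongest peaks (chemoreceptors lost), and 0 to 2 with 1 replicate left out. The non-coding classes numbered 1 to 2 in the same way, with transfer RNA added without replicate 1. Depth is unknown, so a peak missing from 1 replicate cannot be read as absence of binding.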

Other observations

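The tests of extra copies of the unc-42 and ces-1 regions were chosen after the peaks there had been seen, as were the tests between sets of peaks and the set of genes at shared peaks. TAATTA was tested because unc-42 encodes a homeodomain factor, and AGAGAG and CTGCGTCTC because they had stood out at the summits. Of the 94 shared peaks, 46 (48.9%, 95% interval 38.5 to 59.5) had their summit in a promoter window, against 25.6% at random (two-sided permutation of peak positions, p = 0.0002, the smallest possible). Outside the shared set 113 of 277 peaks of replicate 1 (40.8%) and 69 of 276 of replicate 2 did so (Fisher's exact test against the shared peaks, two-sided, p = 0.185 and p = 2.99e-05). Of the shared summits 0 lay in coding exons, which allows a share of up to 3.19%. After unc-42 and rpl-3, the genes with the strongest shared promoter peaks in replicate 1 included C37A2.8 (signal 88.2), nspc-17 (71.8), mrck-1 (63.3), the amyloid precursor-like gene apl-1 (61.3) and lin-18 (51.4). The glutamate receptor gene glr-1 had a shared promoter peak too, but not one of the strongest. It ranked 152 in replicate 1 (signal 30.6), below several genes not named here, and was picked without a test. A longer sequence, CTGCGTCTC, lay within 100 bp of 31 of 371 optimal summits (8.36%), against 1.08% of flanks and 2.67% of promoter positions matched on GC content. The share was 8.89% in the 371 strongest peaks of replicate 1 and 3.50% in those of replicate 2, against 0.674% and 0.539% of their flanks.

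Weak peaks, those more than 1000 bp from any optimal peak, were numerous around unc-42. The number of them in the 40 kb around unc-42 was at or above the 99.3653 percentile of genome windows in both replicates, while their median signal was at the 82.3 percentile in replicate 1 and the 97.8 in replicate 2, and the number around unc-119, which the labels name in the construct, was at 47.9 and 84.9. The number lay at the 14.3293 percentile around ces-1 in replicate 1, on the side foreseen without extra copies of that region. The window around unc-119 lay on the same side, although the labels name that gene in the construct. The measure can therefore miss extra copies, and it does not decide whether the ces-1 region has them. Around 15 other strong peaks the median percentile was at most 57.3671 in either replicate, with single windows up to 96.6 in replicate 1 and 93.9 in replicate 2. This argues against weak peaks gathering at every peak of that strength. Those peaks had signals of at most 125, so gathering that grows with the strength of the peaks, which is greater at unc-42, stays open. The numbers of weak peaks, more than their signal, are consistent with extra copies of the unc-42 region in the worms, as a transgene of that region would give, and a mislabelled strain is then a possible explanation. The lists cannot show which protein carried the tag, and true binding spread over the region stays open, since copy number would need reads. The readings on extra copies, at unc-42 and at ces-1, also assume that the control file did not hold the same copies, which was not checked.

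The sequence at the summits was weighed against known binding sequences and base composition. The upper 95% bound of the Snail E-box difference, -2.42588 percentage points, argues against most of these peaks forming through CAGGTG, and that of the homeodomain core TAATTA, 1.07817 points, against most forming through that sequence. Against promoter windows matched on GC content TAATTA turned to 1.63 points more at summits (95% bootstrap interval -0.876 to 4.29, permutation p = 0.231), so whether it is rarer or commoner there is open. GC content as the whole cause of the GA-rich hexamers is argued against by AGAGAG, which was in 41.0% of summit windows and 14.003% of promoter windows matched on GC content, with a lower 95% bound of the difference of 21.9404 points. A GA-binding factor or open chromatin bound by many factors may lie behind the pattern, and neither was tested, since control libraries were not analysed here.

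The replicates shared 25.34% of their strongest peaks, and the peaks outside the shared set differed in kind. Summits of the 276 peaks of replicate 2 outside it fell in coding exons at 26.4%, which is 1.38971 times the random share (ratio interval 1.12 to 1.69, permutation p = 0.003), while those of the 277 of replicate 1 did so at 0.722% against 18.7%. This argues against placement at random, yet the weaker peaks of replicate 2 also lay in coding exons at 23.9% (Fisher's exact test of the difference, two-sided, p = 0.322), so that these peaks may be mostly unenriched background that itself favours exons. Their share of AGAGAG, 18.1% against 11.96% of flanks (permutation p = 0.0302), leaves room for some enriched peaks among them. Windows matched on GC content were not compared for these peaks, so base composition may also account for that share. A biological difference between the replicates was not tested, as the labels give none.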
